A study of Medicago truncatula with 8 samples.

How the data were processed

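The series profiled nuclei from Medicago truncatula roots of 2 genotypes, wild-type Jemalong A17 and the hypernodulating mutant sunn-4, at 0, 24, 48 and 96 h after the roots were given Sinorhizobium meliloti, the bacterium that forms nitrogen-fixing nodules with this plant. Each of the 8 combinations of genotype and time had 1 library, so no group held replicate libraries. Per the labels' protocols, root segments were chopped, nuclei were stained with DAPI, sorted by flow cytometry and loaded on a 10x Genomics droplet device, and 3' cDNA libraries with unique molecular identifiers (UMIs) were made. Cell Ranger 7.0 is named in the submitters' processing notes. The genome build and annotation behind the counts are not given in the sources used here.

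The deposited values are counts per the file headers and the values themselves: each library came as a sparse matrix of whole-number UMI counts, with 49258 gene identifiers and 10000 barcodes. Barcodes in every library reached down to between 153 and 277 UMIs, so the matrices held droplets well below the depth used for nuclei. Total UMIs per library ran from 4311102 in sunn-4 at 48 h to 10022085 in sunn-4 at 96 h. The identifiers of the deposited files carry no gene names, and 0 of the 49258 matched the 39590 rows of the RefSeq gene table used here. Genes are therefore given by identifier, clusters by number, and at most 2 identifiers that rose and 2 that fell per comparison.

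Barcodes with at least 500 UMIs were kept as nuclei. Scrublet, as run in scanpy 1.11.5 on each library with an expected doublet rate of 6%, called 16 of 30425 barcodes (0.0526%). A caller that marks so few has not worked, so doublets remain among the 30409 retained nuclei. Counts were scaled to 10000 UMIs per nucleus and log-transformed, 2000 highly variable genes were chosen by library, values were scaled within each library, and 30 principal components with 15 neighbours fed Leiden clustering (leidenalg 0.10.2) at resolution 1. Leading genes of a cluster were ranked by the ratio of its CPM to that of all other nuclei, with 10 CPM added to both.

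For tests, UMI counts were summed over the retained nuclei of each library. The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter, an additive design of time point and genotype with 3 residual degrees of freedom, and Benjamini-Hochberg adjustment at 0.05, two-sided. It gave 5 contrasts: sunn-4 against A17 (4 libraries each), the mean of the 3 inoculated times against 0 h (6 libraries against 2), and 24, 48 and 96 h each against 0 h (2 libraries each). The libraries of the other genotype or time serve as replicates in these contrasts, so a response that differs between the genotypes adds to the error. Nothing in the labels says whether libraries came from separate plantings, and inoculation cannot be separated from time after 0 h. A response by genotype and time was given as values only, with exact Poisson intervals at 95% that cover counting error only. A fold against a group at 0 UMIs was taken against a floor of 3 counts over that group.

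Shares of nuclei per cluster carry Clopper-Pearson intervals at 95%, which cover counting error only. The genotype difference in a share was tested by an exact permutation test that swaps genotypes within time points, with 16 sign assignments, whose smallest two-sided p is 2 of 16. Genes within clusters were tested by the same edgeR design on counts summed per library and cluster, for the 17 clusters with at least 20 nuclei in every library. Of 16 gene lists fixed before the data were examined, 15 rest on gene names and were not tested. The list of organelle-encoded genes, marked by the CP and MT prefixes of 128 and 186 identifiers, was tested with camera (limma 3.58.1, preset correlation 0.01), camera with an estimated correlation, and fry. The 11 sets of cell type markers also rest on names and were not used here.

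The rule for identifiers named in the text was fixed before the data were examined for the genotype and inoculation contrasts: the largest log2 fold changes in each direction among genes with an adjusted p under 0.05, a mean of at least 5 CPM and the same sign at all time points or in both genotypes. It also asked for a gene name, a part that had to be dropped, and it was extended afterwards to 48 and 96 h. Clusters discussed by number, and 3 identifiers described in the closing section, were chosen after their values were seen. The alternatives tried were a minimum of 1000 UMIs, every barcode, doublets kept, DESeq2 size factors, no low-count filter, the Wald test of DESeq2 1.42.0, organelle genes left out, no blocking factor, each library left out, and other clusterings (resolutions 0.5 and 2, scaling over all libraries, nuclei thinned to 500 UMIs). Added after the data were seen were the removal of the 6% highest doublet scores, the fit without both 96 h libraries, a clustering without genes that responded, the 96 h contrast within clusters, and an edgeR quasi-likelihood test of nuclei per cluster without a dispersion trend.

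The tests were run first on simulated counts with 200 changed genes. For genotype over 22287 genes, 96 of 100 genes changed 4-fold and 44 of 100 changed 2-fold were recovered, with 21 false calls. For 96 h over 22285 genes, 83 of 100 genes changed 4-fold and 11 of 100 changed 2-fold were recovered, with 8 false calls. For 24 h over 22253 genes, 76 of 100 changed 4-fold and 10 of 100 changed 2-fold were recovered, with 3 false calls. Of all calls in these simulations, false ones were more than 0.05 for genotype, for 96 h and in 2 further contrasts, with 10 false calls each for inoculation and for 48 h, so the genotype count in particular may hold more false calls than its threshold states.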

Results

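Nuclei were profiled from roots of wild-type A17 and of sunn-4, a mutant that forms more nodules than the wild type, before inoculation with Sinorhizobium meliloti and 24, 48 and 96 h after it. The 8 libraries, 1 per genotype and time, gave 30409 retained nuclei with a median of 978 UMIs. Retained nuclei numbered 3586, 3487, 3870 and 4422 in A17 at 0, 24, 48 and 96 h, and 6147, 2215, 2095 and 4587 in sunn-4. Their summed UMIs ran from 1677294 in sunn-4 at 48 h, the shallowest library with a median of 671 UMIs per nucleus, to 8404835 in sunn-4 at 96 h, the deepest with a median of 1341. The level of the mutated gene was not analysed here, because the files do not pair identifiers with gene names.

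The first comparison asked which genes differed between sunn-4 and A17 whatever the time. Of 22721 genes tested, 5 were higher and 18 lower in sunn-4, several of them switched almost fully between the genotypes. MtrunA17Chr4g0028661 had 3666 UMIs over the 4 A17 libraries and 3 over the 4 sunn-4 libraries, a ratio of 1431 (95% counting interval 489 to 6944; edgeR adjusted p = 0.00018). Its level was 193 to 218 CPM in each A17 library. MtrunA17Chr5g0402891 had 2270 UMIs in A17 and 2 in sunn-4, a ratio of 1330 (95% counting interval 368 to 10985; adjusted p = 0.00018). In the other direction, MtrunA17Chr8g0358691 had 461 UMIs in sunn-4, at 16.3 to 32.8 CPM per library, and 0 in A17, at least 131-fold higher (adjusted p = 0.0264). MtrunA17Chr2g0324011 had 949 UMIs in sunn-4 and 22 in A17, 36.8-fold higher (95% counting interval 24.2 to 59.0; adjusted p = 0.0208). Leaving out A17 at 0, 24 or 48 h gave 6, 13 and 12 genes, and leaving out sunn-4 at 0, 24 or 48 h gave 9, 12 and 13. DESeq2 called 88 genes. An effect of the sunn-4 mutation cannot be told apart here from other differences between the plants of the genotypes. Switched genes were also seen within A17. MtrunA17Chr8g0354631, picked after its values were seen, had 222 UMIs in A17 at 0 h and 0 in A17 at 48 h.

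The next comparisons asked which genes changed after inoculation. Few genes passed over the 3 inoculated times together: 4 were higher and 1 lower than at 0 h. MtrunA17Chr6g0469911 had 0 UMIs in both 0 h libraries and was detected in both genotypes from 24 h on. In A17 it reached 9.46 CPM at 24 h (95% Poisson interval 6.87 to 12.7), 35.8 at 48 h (30.5 to 41.7) and 89.7 at 96 h (81.1 to 98.9). In sunn-4 the same gene reached 7.89 CPM (5.00 to 11.8), 40.5 (31.5 to 51.4) and 49.5 (44.9 to 54.5). With 1117 UMIs over the inoculated libraries, it was at least 174-fold higher than at 0 h with the genotypes pooled (edgeR adjusted p = 0.0364). MtrunA17Chr1g0197491 rose 97.1-fold in UMIs pooled over libraries (95% counting interval 51.1 to 213), with a fitted log2 change of 5.84 that weighs the 3 times equally (adjusted p = 0.0364), from 0.691 CPM at 0 h to 69.6 CPM at 96 h in A17 and from 0.737 to 142 CPM in sunn-4. MtrunA17Chr6g0487981 fell 3.49-fold in pooled UMIs (95% counting interval 3.00 to 4.07), with a fitted log2 change of -2.57, a larger fall (adjusted p = 0.0468), from 47.9 CPM at 0 h to 0.890 CPM at 96 h in A17 and from 30.6 to 1.31 CPM in sunn-4. The count for inoculation moved with every library left out. It was 0 without A17 at 0 h, sunn-4 at 0 h or sunn-4 at 48 h, 1 without A17 at 24 h and 3 without sunn-4 at 24 h. It was 64 without sunn-4 at 96 h, 139 without A17 at 96 h and 160 without A17 at 48 h, and DESeq2 called 348.

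**Figure D1:**
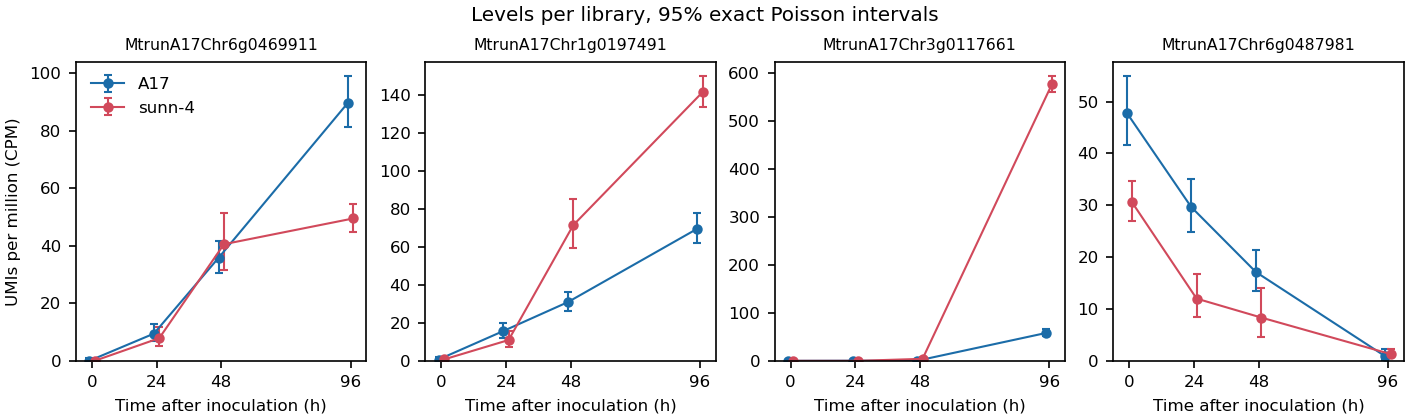
Level in CPM (vertical axis, linear, from 0) of 4 genes against time after inoculation in h, 1 point per library, with 95% exact Poisson intervals that cover counting error only. MtrunA17Chr6g0469911 and MtrunA17Chr1g0197491 lie above their 0 h level from 24 h on in both genotypes, MtrunA17Chr3g0117661 reaches 58.3 CPM in A17 and 577 CPM in sunn-4 at 96 h, and MtrunA17Chr6g0487981 declines to 0.890 and 1.31 CPM.

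At 24 h taken alone, edgeR called 0 genes against 0 h, with 984 genes at an unadjusted p under 0.05, and DESeq2 called 16. At 48 h edgeR called 3 genes, all higher, and DESeq2 called 65. Both identifiers that rose over the inoculated times were among the 3: MtrunA17Chr6g0469911 was at least 154-fold (genotypes pooled) and MtrunA17Chr1g0197491 58.1-fold higher (edgeR adjusted p = 0.0338 and 0.0418). The count at 48 h was 0 without any 1 of the libraries A17 at 0 h, sunn-4 at 0 h, A17 at 48 h and sunn-4 at 48 h.

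By 96 h, 672 genes were higher and 814 lower than at 0 h. All 3 genes called at 48 h were among the 672, where 0.0887 would be shared by independent lists, although both contrasts use the same 0 h libraries and part of the excess may come from them. MtrunA17Chr3g0117661 went from 0 UMIs in both 0 h libraries to 262 in A17 and 4846 in sunn-4 at 96 h, at least 1648-fold higher with the genotypes pooled, a bound that rests mostly on sunn-4 (edgeR adjusted p = 0.00466). Its level at 96 h was 58.3 CPM in A17 (95% Poisson interval 51.4 to 65.8) and 577 in sunn-4 (560 to 593). MtrunA17Chr5g0424971 was at least 502-fold higher, again pooled and mostly from sunn-4 (adjusted p = 0.00796), at 19.1 CPM in A17 and 175 in sunn-4. MtrunA17Chr4g0044901 fell from 203 UMIs at 0 h to 2 at 96 h, 105-fold (95% counting interval 28.7 to 872; adjusted p = 0.0118). MtrunA17Chr6g0484811 fell from 153 to 2 UMIs, 79.1-fold (95% counting interval 21.5 to 659; adjusted p = 0.0187). The count depended on single libraries: it was 24 without sunn-4 at 0 h, 256 without A17 at 0 h, 601 without sunn-4 at 96 h and 2861 without A17 at 96 h, against 1486.

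Set side by side, the log2 changes of the genotypes correlated more at 96 h than before. Across 11913 genes with a mean log2 CPM of at least 4, the log2 change from 0 h in A17 and that in sunn-4 had a Pearson r of 0.617 at 96 h (Spearman rho 0.493), 0.215 at 48 h (0.104) and 0.258 at 24 h (0.203). These are correlations across genes, which are not independent replicates, between changes that share no library. The sunn-4 libraries held 2916606 UMIs at 24 h and 1677294 at 48 h, against 8404835 at 96 h. Depth was not made equal here, so the lower r at 24 and 48 h does not show that the responses were less alike then. At 96 h, 357 genes were at least 2-fold higher in A17 and 655 in sunn-4, with 176 in both, where 19.6 would be shared by independent lists. At least 2-fold lower were 714 in A17 and 1134 in sunn-4, with 500 in both against 68.0. Of the 672 genes called higher at 96 h, 459 (68.3%) had the larger log2 change in sunn-4; 92 of the 672 had under 4 UMIs at 0 h, so that the prior count of 2 enters the size of their change. Of the 814 genes called lower, 449 (55.2%) changed more in sunn-4. With the shares of 16 clusters held at 0 h and all other clusters left out, cluster 9 among them, it was 334 (41.0%). For the 672 it was then 427 (63.5%). Both counts with shares held use CPM with 0.5 added and no TMM factors. Over all nuclei that measure gave 463 of the 672 (68.9%) and 449 of the 814. Holding shares and leaving out clusters cannot be told apart in these values. The difference in response between the genotypes has no replicate check and was not tested.

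Clustering of all nuclei gave 33 clusters. Cluster 9, led by MtrunA17Chr7g0221021 (1499 CPM inside, 39.5 outside) and MtrunA17Chr5g0430991 (382 and 4.35 CPM), grew by 4.72 percentage points in A17 and 16.0 in sunn-4 by 96 h. It held 0.725% of A17 nuclei at 0 h (95% Clopper-Pearson interval 0.474 to 1.06) and 5.45% at 96 h (4.80 to 6.16). In sunn-4 it held 1.11% at 0 h (0.860 to 1.40), 3.53% at 48 h (2.78 to 4.41) and 17.1% at 96 h (16.0 to 18.2). Genes that define this cluster also respond over time, so the nuclei were clustered again without 6806 genes that had an unadjusted p under 0.05 in any comparison. The matching cluster then went from 1.12% to 5.04% in A17 and from 1.46% to 17.9% in sunn-4. Each new cluster was matched to the first cluster that held most of its nuclei, so these shares are not independent of the first clustering. Of all nuclei, 57.9% lay in the cluster matched to their first one. Cluster 23, led by MtrunA17Chr3g0105311 and MtrunA17Chr3g0135321, went from 0.251% to 0.905% in A17 and from 0.293% to 3.58% in sunn-4, and from 0.446% to 0.972% and 0.586% to 4.25% without those genes.

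Other clusters shrank. Cluster 4, led by MtrunA17Chr8g0346561 and MtrunA17Chr7g0220161, went from 10.8% to 2.62% in A17 and from 8.07% to 2.79% in sunn-4 between 0 and 96 h. Without the responding genes it went from 6.36% to 1.67% and from 5.32% to 1.85%. Cluster 6, led by MtrunA17Chr1g0203351 and MtrunA17Chr6g0449521, fell to 1.36% in A17 and 0.894% in sunn-4 at 96 h, from 2.84% and 7.22% at 0 h. Its share in A17 was 9.03% at 24 h, above that at 0 h. Between genotypes over all times, the exact permutation test reached the smallest p that 16 sign assignments can give, 2 of 16, for 5 of the 33 clusters, which is above 0.05 whatever the values. Of the 5, clusters 5, 11, 25 and 30 had lower shares in sunn-4 than in A17 at all 4 times. In cluster 1 alone the share in sunn-4 was above A17 at all 4 times, by a mean of 2.30 percentage points ± 3.18 (SD, n = 4). It was 24.2% against 17.2% at 48 h, where nuclei of sunn-4 were shallowest. The direction turned with doublets kept (mean of -1.03 points), and with scaling over all libraries the mean was 0.187. By the design fixed beforehand, shares over time were to be given as values only.

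A test of shares over time was nevertheless run after they were seen: edgeR quasi-likelihood on nuclei per cluster, with the same additive design and library totals. At 96 h it called 6 of the 33 clusters higher and 4 lower than at 0 h. Without sunn-4 at 0 h it called 0, with 8 at an unadjusted p under 0.05, and without A17 at 24 h or sunn-4 at 24 h it called 4 higher and 0 lower. Cluster 9 had a log2 change of 3.48 (adjusted p = 0.00605), cluster 23 of 2.96 (0.0241), cluster 4 of -1.76 (0.0244) and cluster 6 of -2.12 (0.0241). Without sunn-4 at 96 h the change of cluster 23 was 1.38 and without A17 at 96 h 3.92, and that of cluster 6 was -1.22 without sunn-4 at 0 h and -2.83 without A17 at 0 h. Each of these 4 calls was lost with some library left out. For cluster 9 the call was lost without sunn-4 at 0 h (edgeR adjusted p = 0.0684). For cluster 23 it was A17 at 0, 24 and 48 h (0.0560, 0.0730 and 0.0733) and sunn-4 at 0, 24, 48 and 96 h (0.121, 0.0730, 0.0732 and 0.187). For cluster 4 it was A17 at 0, 24 and 96 h (0.0708, 0.0730 and 0.0669) and sunn-4 at 0 and 24 h (0.121 and 0.0730). For cluster 6 it was A17 at 24 and 48 h (0.0730 and 0.0792) and sunn-4 at 0, 24, 48 and 96 h (0.239, 0.0730, 0.0792 and 0.0710). In these fits the change of cluster 9 was 3.27 and that of cluster 4 -1.46 to -1.78. That of cluster 23 was 2.89 to 2.99 apart from the 1.38 without sunn-4 at 96 h. That of cluster 6 was -2.09 to -2.10 apart from -1.22 without sunn-4 at 0 h and -1.64 without sunn-4 at 96 h. The other clusters called at 96 h, 11, 17, 18, 19, 26 and 32, were not recovered as separate clusters without the responding genes. Their sizes are not compared here, so the losses above hold for the 4 clusters only. Cluster 19 was also called higher after inoculation (edgeR log2 change 2.33, adjusted p = 0.0163) and at 48 h (2.37, adjusted p = 0.0297). Both calls were lost with some libraries left out, and the call at 48 h also with a dispersion trend.

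**Figure D2:**
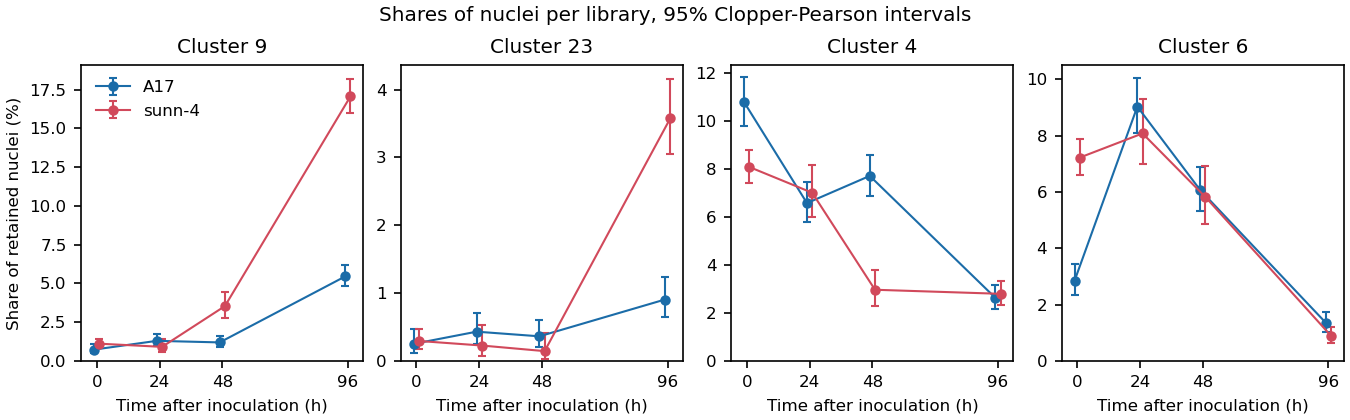
Share of retained nuclei in % (vertical axis, linear, from 0) in clusters 9, 23, 4 and 6 against time after inoculation in h, 1 point per library, with 95% Clopper-Pearson intervals that cover counting error only. Cluster 9 ends at 5.45% in A17 and 17.1% in sunn-4, and cluster 4 at 2.62% and 2.79%.

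Levels per cluster are given here for 2 of the identifiers that rose. MtrunA17Chr3g0117661 ranked 3 among the leading genes of cluster 9. The clusters came from the same counts, so its gathering in that cluster may be partly built in. At 96 h, cluster 9 gave 69.8% of its UMIs in A17 and 67.7% in sunn-4, at 776 CPM (95% Poisson interval 667 to 897) and 1782 CPM (1721 to 1844). The next highest level was in cluster 21, at 392 CPM in A17 (232 to 619) and 918 in sunn-4 (696 to 1190), and cluster 26 had 222 and 784 CPM. In cluster 7, 1 of the lowest, it was 0 UMIs of 409351 in A17, which allows up to 9.01 CPM, and 54.9 CPM (35.5 to 81.0) in sunn-4. Over clusters other than 9, 18, 19, 23, 26 and 32 the median was 0 CPM in A17 and 204 CPM in sunn-4. The median in A17 does not show absence, since 0 UMIs in a small cluster allow much more, up to 365 CPM in cluster 27. Clusters 1 and 2, with the most UMIs in A17 at 96 h, had 25.8 and 15.1 CPM. Barcodes under 500 UMIs held MtrunA17Chr3g0117661 at 66.9 CPM in A17 and 696 CPM in sunn-4 at 96 h. Its levels outside cluster 9 may thus hold RNA from outside the nuclei, which was not separated. They do not show expression there. MtrunA17Chr6g0469911, the gene seen from 24 h on, was highest at 96 h in cluster 15, led by MtrunA17Chr1g0194511 and MtrunA17Chr5g0425621. Its level there in A17 was 0 UMIs at 0 h, 394 CPM at 24 h (247 to 596), 796 at 48 h (642 to 975) and 1059 at 96 h (912 to 1223). In sunn-4 it was 0 UMIs at 0 h, 225 CPM at 24 h (103 to 428), 224 at 48 h (96.8 to 442) and 1491 at 96 h (1284 to 1721). Cluster 19 held 22.8% of its UMIs in A17 and 23.6% in sunn-4 at 96 h, at 733 and 540 CPM, and in sunn-4 at 48 h its level there, 444 CPM (243 to 745), was above that in cluster 15. In cluster 9 the gene stood at 76.3 CPM in A17 and 37.5 CPM in sunn-4 at 96 h.

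Within the 17 clusters with enough nuclei, 65 genes differed between sunn-4 and A17 in at least 1 cluster, 26 of them higher and 39 lower, and 19 of the 23 genes called over all nuclei were among them. After inoculation 243 genes changed in at least 1 cluster, with 79 higher and 164 lower. Cluster 15 had the most higher genes, 48, against 14 lower, of 3707 tested. Cluster 11 had the most lower genes, 75, against 5 higher, of 6009 tested. Cluster 3 had 23 higher and 57 lower, of 10789 tested. Between 96 and 0 h, a contrast added after the data were seen, 1449 genes were called in at least 1 cluster and 533 in more than 1, and 667 of the 1486 genes called over all nuclei were among them. Called genes numbered 335 higher and 315 lower of 10789 tested in cluster 3, and 241 and 176 of 11847 in cluster 1. In cluster 9 they numbered 65 and 28 of 1565. Genes tested ran from 1046 in cluster 21 to 12077 in cluster 2, and UMIs differed too. The counts therefore do not rank the clusters by their response. RNA from outside the nuclei was not separated from these counts. The 92 genes called higher over all nuclei at 96 h with under 4 UMIs at 0 h made up 3584 CPM of barcodes under 500 UMIs in sunn-4 at 96 h and 845 CPM in A17. With a minimum of 1000 UMIs, 4 clusters could be tested and 25 genes were called for genotype and 20 after inoculation, and at resolution 0.5 the inoculation count was 421.

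**Figure D3:**
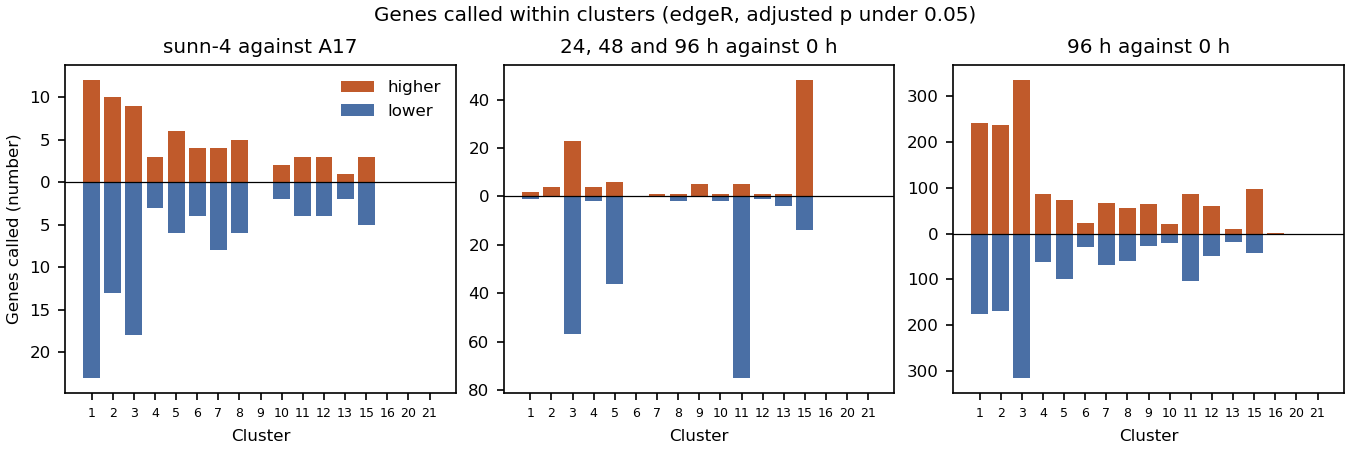
Number of genes called higher (upward bars) and lower (downward bars) by edgeR at an adjusted p under 0.05 within each of 17 clusters (horizontal axis), for sunn-4 against A17, for 24, 48 and 96 h against 0 h, and for 96 h against 0 h; vertical scales differ. Cluster 15 has 48 higher genes after inoculation, and cluster 3 has 335 higher and 315 lower genes at 96 h. Genes tested differ between clusters, from 1046 in cluster 21 to 12077 in cluster 2, so bar heights do not rank the clusters by their response.

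Organelle-encoded genes were the 1 list whose members the identifiers mark. The libraries were made from sorted nuclei, and how much organelle RNA was carried along with them was not measured. Changes in this list are therefore not read as regulation. After inoculation, 0 of its 165 measured members passed singly, and 0 passed adjusted over the list alone. The list's median log2 change was 0.28, and camera with a preset correlation gave p = 1.33e-08, upward. The p was 0.333 with an estimated correlation and 0.275 with fry, so the call rests on the preset correlation, and it was 0.534 without sunn-4 at 0 h. Between genotypes the median log2 difference was 0.13, upward in sunn-4, with camera p = 0.00644, lost with an estimated correlation (0.583) and with fry (0.498), and in an exact permutation of the genotypes within time points 5 of the 8 splits gave a camera p as small. The 93 members with the MT prefix had a median of 0.00 and the 72 with the CP prefix 0.39, so the upward median comes from the latter. The call for the whole list was also lost without A17 at 48 h (0.345) and without sunn-4 at 48 h (0.351), and its direction turned without A17 at 96 h (0.587) or sunn-4 at 96 h (0.490). UMIs with the CP prefix made up 0.312% of all UMIs in sunn-4 at 96 h (95% Clopper-Pearson interval 0.308 to 0.315) and 0.118% to 0.202% in the other 7 libraries.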

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

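The test of free RNA was chosen only after the result was seen, that of wrongly placed nuclei after levels of top genes per cluster but not its own value had been seen, and the use of an interval beside the bounds for depth and cluster shares was decided after their values were seen. Groups of 1 library allow no check for a sample far from others of its group.

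The share of cluster 14, led by MtrunA17Chr4g0020031 and MtrunA17Chr4g0066581, moved in opposite directions between 0 and 96 h: by 2.57 percentage points in A17 (from 1.25% to 3.82%) and by -1.39 points in sunn-4 (from 2.07% to 0.676%). With nuclei thinned to 500 UMIs the change in sunn-4 turned to 1.08 points, so that both genotypes rose (2.83 in A17). The difference was not tested, since each value is 1 library against 1. Opposite changes of at least 2-fold at 96 h were found for 19 of 11913 genes, likewise untested. Changes of that size in the same direction were found for 176 genes higher and 500 lower in both genotypes. The 19 are few beside these, and they are not read as a difference between the genotypes.

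Barcodes under 500 UMIs, which are not among the retained nuclei, held MtrunA17Chr3g0117661 at 66.9 CPM in A17 (95% Poisson interval 55.3 to 80.2) and 696 CPM in sunn-4 (655 to 738) at 96 h. In the same kind of barcodes at 0 h it had 0 UMIs, which allows up to 2.04 CPM in A17 and 2.74 CPM in sunn-4. The retained nuclei at 96 h had 58.3 and 577 CPM.

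The 92 genes called higher at 96 h with under 4 UMIs at 0 h were counted in all 16 tested clusters other than cluster 9, in sunn-4 at 425 to 4433 CPM, against 8329 CPM in cluster 9 and 3584 CPM in barcodes under 500 UMIs. Free RNA from 1 source would keep the genes in the same ratio everywhere, yet their proportions differed between clusters. The chi-square per degree of freedom was 4.71 in sunn-4 and 2.52 in A17, where the highest of 1000 permutations gave 1.27 and 1.28. This argues only against free RNA as the source of every count of the 92 genes. A few genes can give such a value. In sunn-4, MtrunA17Chr6g0469911, 1 of the 92, had 186 of 124757 UMIs in cluster 15 and 0 of 455593 in cluster 7. For the other genes the value does not decide on free RNA, since it was taken over the whole set. Nuclei of an expanding cluster placed in the wrong cluster may add to the signal. The share of nuclei with a UMI of the 92 genes was 0.862 of the share expected if UMIs were spread by depth. That lies between the bounds set for either reading. Free RNA as part of the signal and expression in several cell types also stay open, and whether barcodes under 500 UMIs hold free RNA or shallow nuclei was not tested.

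At 96 h the genes called higher changed more in sunn-4 than in A17 for 459 of 672. Library depth as the source of the larger size is argued against for these 672 genes only. The next values use CPM with 0.5 added and no TMM factors, by which it was 463 (68.9%) over all nuclei. With the 0 and 96 h libraries thinned to 4343949 UMIs each, 69.2% of the genes still changed more in sunn-4. That is above the bound of 60% set beforehand, with a 95% binomial interval of 65.6 to 72.7 that treats genes as independent. The genes had been called at full depth, where sunn-4 was deeper, so thinning does not test an effect of depth on which genes were called. With the shares of 16 clusters held at 0 h and all other clusters left out, cluster 9 among them, 63.5% changed more in sunn-4. That is past the same bound of 60%, but its interval of 59.8 to 67.2, a criterion added after the values were seen, reaches below it. The median log2 changes, with 0.5 CPM added, were 1.59 in A17 and 1.99 in sunn-4, against 2.04 and 2.44 over all nuclei. For the genes called lower, the percentage that changed more in sunn-4 turned from 55.2% to 41.0% with shares held. Most genes called higher thus still changed more in sunn-4 with shares held. The interval lies above a lower bound, also set beforehand, under which cluster shares were to count as the cause. It reaches below the 60% set against that cause and treats genes as independent, so no verdict on cluster shares is drawn. The genotype itself stays open, untested.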

How the results depend on the processing

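Chosen only after results were seen were the fits without the highest doublet scores and without both 96 h libraries, the clustering without responding genes and the test of nuclei per cluster. Counts of called genes moved with the tool and the filter. The cause was not tested except where fewer libraries or genes explain it by construction. With DESeq2 the counts were 88 for genotype, 348 after inoculation, 16 at 24 h and 65 at 48 h. Without a low-count filter they were 93, 311, 9, 51 and, at 96 h, 2523. For inoculation the count was 17 at a minimum of 1000 UMIs, 14 with every barcode, 13 with DESeq2 size factors, 13 without organelle genes, 1 without the genotype block, 15 without the highest doublet scores, and 0 without both 96 h libraries. At 48 h it was 0 with every barcode and 1 without the genotype block. With each library left out in turn the counts ranged from 6 to 21 for genotype, 0 to 160 after inoculation, 0 to 4 at 48 h and 24 to 2861 at 96 h, and stayed at 0 at 24 h. A group left with 1 library is then assumed to vary like the rest. Of the 1486 genes called at 96 h, 1485 were also called without a filter, 1396 with DESeq2, 1282 with every barcode, 1179 without the genotype block, 1123 at a minimum of 1000 UMIs, and from 23 (without sunn-4 at 0 h) to 1294 (without A17 at 24 h) with 1 library left out.

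The p of the organelle list ranged from 2.36e-06 to 0.587 for genotype and from 2.72e-13 to 0.534 after inoculation with each library left out, and the genotype direction turned without A17 at 96 h (0.587) or sunn-4 at 96 h (0.490). With an estimated correlation it was 0.583 and 0.333, and with fry 0.498 and 0.275.

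The changes in the shares of clusters 9, 23, 4 and 6 kept their direction in all 7 other clusterings. Beyond the spread of the genotypes, cluster 23 moved to a mean of 4.82 points with scaling over all libraries, and cluster 4 to -11.4 at resolution 0.5, -10.5 with scaling over all libraries and -4.08 without responding genes. The change of cluster 14 in sunn-4 reversed to 1.08 with nuclei thinned to 500 UMIs, and it moved beyond counting error in 1 other planned clustering. The change of cluster 14 in A17 kept its direction but moved beyond counting error in 2 planned clusterings and 1 added clustering. Cluster 1 between genotypes went to -1.03 with doublets kept. Genes within clusters went to 25 for genotype and 20 after inoculation at a minimum of 1000 UMIs, where 4 clusters were tested, and to 421 after inoculation at resolution 0.5. The shallow sunn-4 library of 48 h, with 345 barcodes of at least 1000 UMIs, limits what can be seen at that time. The test of nuclei per cluster at 96 h, run after the shares were seen, called 6 clusters higher and 4 lower, and the same numbers with TMM factors and with a dispersion trend. It called 0 clusters for genotype, 1 after inoculation, 0 at 24 h and 1 at 48 h, and with the trend 1 for genotype, 2 higher and 2 lower after inoculation, and 0 at 24 and 48 h. With the trend, a version tried last, adjusted p was 0.00219 for cluster 9, 0.0120 for cluster 23 and 0.00443 for clusters 4 and 6. No paired analysis was possible by replicate number, because groups share only 1 such number. The genotypes were compared within time points instead, and without the time block 26 genes were called for genotype.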

Other observations

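All tests in this part, and the 3 genes named first, were chosen only after the values were seen. MtrunA17Chr8g0354631 had 222, 160 and 168 UMIs in A17 at 0, 24 and 96 h, but 0 in A17 at 48 h and 0 in every sunn-4 library. MtrunA17Chr4g0029981 had 73, 56 and 89 UMIs in the same A17 libraries and 0 at 48 h, and MtrunA17Chr4g0025031 had 18, 24 and 31 and again 0.

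From the other A17 libraries, 186, 73.6 and 24.6 UMIs were expected at 48 h, which argues against low depth. A mislabelled library is argued against by the 13 genes that part the genotypes at 0, 24 and 96 h: at 76.9% of them it lay on the A17 side, and the other 7 libraries lay on their own side at all of their 9 to 13 genes. A mixture with sunn-4 nuclei is argued against by the median level of the A17 genes, 0.879 of that in the other A17 libraries, while 2 of 11 were at 0. A candidate explanation left open is seed that differs at a few loci from the plants of the other times, which was not tested.

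Of 12 genes called between genotypes with an absolute log2 change above 4, 4 have identifiers of chromosome 4, where 1.94 would be expected from the genes tested (exact hypergeometric p = 0.114, one-sided), so no excess was shown.

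Other splits of the genotype labels within time points, 8 with the real one, gave 0 genes at most where the real split gave 23, and within clusters 13 genes at most where the real split gave 65. In each case 1 of 8 splits, the real one, gave as many, and 8 splits are too few for a share under 0.05. For organelle-encoded genes, 5 of the 8 splits gave a camera p as small as 0.00644, the smallest other being 5.06e-18.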
